A study of Mus musculus with 16 samples.

How the data were processed

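Whole-retina RNA from C57BL/6J mice was measured in 16 libraries that fall into 6 groups, control and oxygen-induced retinopathy (OIR) at postnatal days 14, 17 and 30 (P14, P17 and P30). In OIR, young mice breathe oxygen-rich air, which stops and prunes retinal vessel growth, and the return to room air leaves the under-vascularised retina short of oxygen. Per the labels' protocols, OIR mice were kept in 75% oxygen from day 7 to day 12 and then in 21%, and control mice stayed in 21%. Control and OIR at P14 have 2 libraries each and the other 4 groups have 3 each. Groups and replicate numbers were taken from the sample titles.

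Per the labels' protocols, RNA was extracted from retina with a column kit, mRNA was selected on Dynabeads, and libraries made with the Ion Total RNA-seq Kit v2 were sequenced on an Ion Proton. The same protocols name Torrent Suite 5.4.0 and its RNA-seq plugin, which aligned reads to mm10 with STAR, aligned the remaining reads with Bowtie2, and counted reads per gene with HTSeq. The versions of the aligners, the gene annotation release and the strand setting of the counting are not given in the sources used here. The deposited values are raw counts, whole numbers per gene symbol, with 43280 symbols in each library, and the authors applied no normalization to them. Because the strand setting is unknown, reads where Fgf2 and its antisense gene Fgf2os overlap cannot be assigned to either. Reads of near-identical genes (Lyz2 and Lyz1, C4b and C4a, H2-K1 and other histocompatibility genes, the Serpina3 family, the crystallins) may be split between copies, so the values of these genes are uncertain.

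Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr over the 6 groups (a minimum count of 10 and a minimum total of 15), which left 19905 genes, and libraries were scaled by TMM. All 16 libraries entered one robust quasi-likelihood fit with 10 residual degrees of freedom, so that the groups of 2 borrow the spread of the others. Each comparison was a quasi-likelihood test with Benjamini-Hochberg adjustment over the tested genes, and a gene was called at an adjusted p under 0.05. The comparisons were OIR against control at each age, the difference of the OIR effect between consecutive ages, and control against control between consecutive ages. Levels are given as CPM scaled by the TMM factors, mean ± SD over libraries. Log2 fold changes have a standard error (SE) computed as the size of the fold change over the square root of its F statistic. For shares of counts in a single library a 95% Wilson interval is given, and a count of 0 was read as up to 3 counts. These intervals cover counting error only, since PCR copies are not independent molecules.

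Before the data were examined, 31 gene lists, the tests, the alternatives and the naming rule were fixed. Lists with at least 5 tested genes entered camera from limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over 90 list by age tests, and the same test was run with an estimated correlation. This left 30 of the lists. For each OIR comparison the rule allows the 8 called genes with the largest rise and the 6 with the largest fall, given an average log2 CPM of at least 1 and every OIR library beyond every control library. It also allows up to 4 members with the smallest p from each list, and always a fixed set with Vegfa, Gfap, Cdkn1a, Cdkn2a, Angpt2, Esm1, Edn2 and Opn1sw. For control ages and differences between ages it allows the 4 largest rises and the 4 largest falls, without the condition on every library for the differences. The text names a part of the genes so allowed, picked after their values were seen, and some genes the rule allows are not reported here. Xist and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, as well as Fam107a, fall outside the rule or were singled out after their values were seen.

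The steps were tested on simulated data with known fold changes, 67 genes each at 1.5-fold and 2-fold and 66 genes at 4-fold per comparison. For P14 (19617 simulated genes) a 2-fold change was recovered in 70.1% and a 4-fold change in 92.4% of changed genes, and 6.45% of calls were false. For P17 (19614 genes) the shares were 80.6%, 95.5% and 4.30%, and for P30 (19642 genes) 77.6%, 98.5% and 4.09%. A 1.5-fold change was recovered in 22.4% of changed genes at P14, 47.8% at P17 and 31.3% at P30. The changed genes were drawn without those at the lowest average levels. The 30 genes of the hypoxia list were also raised 2-fold and counted as true calls. Counts were drawn gene by gene, so lens or Y-linked genes did not move together between libraries of a group. These shares therefore need not hold for the real libraries.

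Alternatives fixed beforehand were RLE scaling, scaling by library totals, no count filter, a stricter filter (50 counts in 2 libraries), DESeq2 1.42.0, limma-voom, a replicate block, fits of only the compared groups, an adjusted p under 0.01, a test against a 1.5-fold change, and leaving out each library. For the lists, fry and the estimated correlation were added. After seeing the data, a lens covariate, a Y-linked covariate, leaving out the lens list and Yam1, leaving out 2 OIR libraries, and a crossed replicate block at P14 were added. Leaving out those 2 libraries keeps OIR replicate 3 as the only OIR library at P17, with its spread taken from the other groups. No pair of replicates was within sampling noise: chi-square per degree of freedom was 13.4 or more in every pair. The labels do not say that replicates are separate animals. In control at P14 and OIR at P30, Xist and Ddx3y reads differ between replicates as between sexes, so these are not all copies of 1 animal. Elsewhere the spread may be technical, and p-values measure only the spread between these samples. Coordinates are on mm10 with GENCODE M21 gene bounds, 1-based.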

Results

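The retina of mice with OIR was compared with that of age-matched controls at P14, P17 and P30. Library totals ran from 26077663 to 41716971 counted reads, and between 24016 and 25420 genes had reads in each library.

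Some properties of the libraries moved with the groups. Genes of the lens list took between 0.00558% (95% Wilson interval 0.00530 to 0.00587) and 9.16% (9.15 to 9.16) of counts. At P17 their share was 8.60% (8.59 to 8.61), 6.30% (6.29 to 6.31) and 0.388% (0.386 to 0.390) in OIR, against 0.0420% (0.0413 to 0.0426) to 0.657% (0.654 to 0.659) in controls, and every P30 library had 3.66% (3.66 to 3.67) or more. The lens list had a median log2 fold change in OIR of -7.39 at P14 and 3.53 at P17 (adjusted p = 0.181 and 0.489 with an estimated correlation). Of its 19 tested genes 0 are in another list, and Cryab, Crybb3, Bfsp1 and Bfsp2 were at 1 CPM or more in the OIR libraries at P14, which hold the least lens RNA. All 3 OIR libraries at P17 had Xist, the RNA of the inactive X chromosome, at 114 to 158 CPM. The Y-linked Ddx3y had 0 reads in 2 of them, which allows up to 0.0858 and 0.0677 CPM, and 1 read in the other. The 3 controls at P17 had Ddx3y at 25.8 to 33.3 CPM and Xist at 0.104 CPM or less. Control replicate 2 at P14 and OIR replicate 2 at P30 also had high Xist (913 and 105 CPM). Yam1, a non-coding RNA, took 0.0898% (0.0888 to 0.0908) to 0.333% (0.331 to 0.335) of counts at P14 and 1.39% (1.38 to 1.39) to 6.83% (6.82 to 6.84) at later ages.

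**Figure D1:**
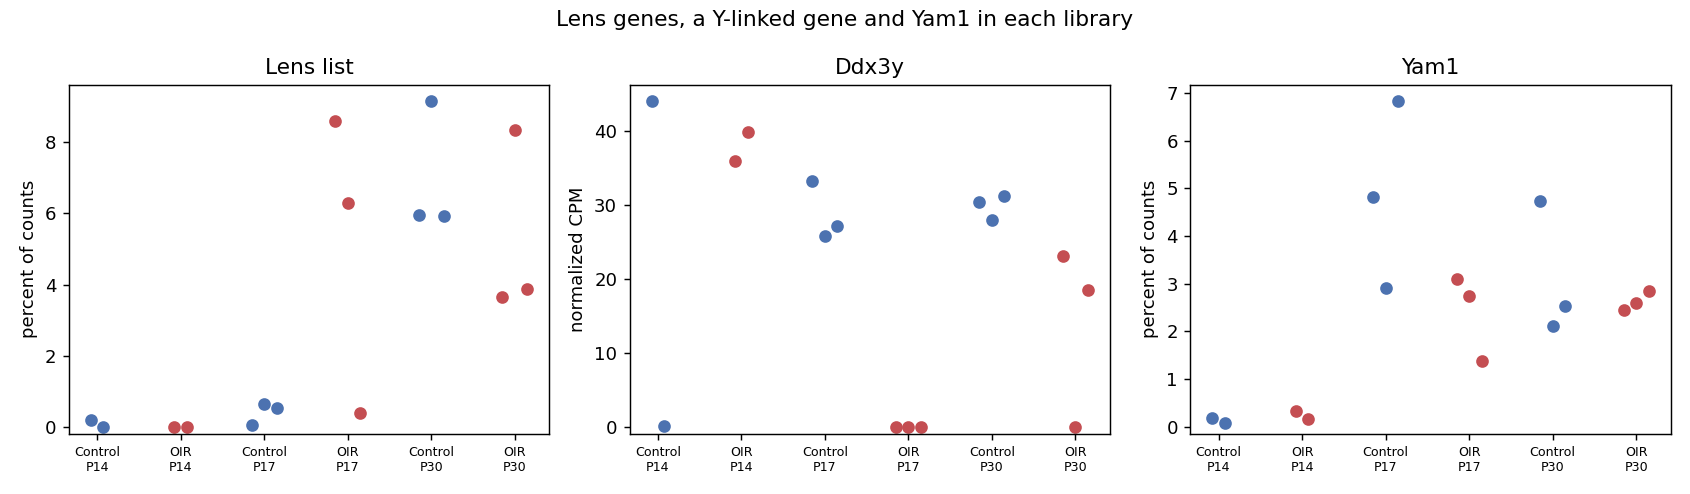
Share of counts from the lens list (percent), Ddx3y (normalized CPM) and share of Yam1 (percent) in each library, with controls in blue and OIR in red. Ddx3y is at 25.8 CPM or more in all 3 controls at P17 and near 0 in all 3 OIR libraries of that age.

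The P14 comparison asks what differed 2 days after the return to room air. Hypoxia-inducible genes and genes of the glial reactivity list rose at P14. Gfap, an intermediate filament of reactive glia, went from 14.6 ± 2.66 to 117 ± 2.40 CPM (SD, n = 2 each), and Vegfa, the main vascular growth factor of the hypoxic retina, from 265 ± 16.2 to 594 ± 4.15 CPM. Edn2, an endothelin made by stressed photoreceptors, went from 0.0893 ± 0.0524 CPM (7 reads in both controls) to 8.51 ± 0.335 CPM. Ndufa4l2, a hypoxia-inducible mitochondrial protein, rose by a log2 fold change of 3.23 (SE 0.281). The edgeR quasi-likelihood test called 144 genes higher and 19 lower, against 48 and 4 with the lens covariate and 93 and 9 with the Y-linked covariate, both chosen after seeing the data. DESeq2 called 275 and 93 genes at P14, a fit of the P14 libraries alone 250 and 32, and edgeR without a count filter 507 and 170, while a test against a 1.5-fold change called 30 and 2. The lens share was 0.00558% (95% Wilson interval 0.00530 to 0.00587) and 0.00602% (0.00575 to 0.00629) in OIR at P14 and 0.189% (0.188 to 0.191) and 0.0108% (0.0105 to 0.0112) in controls.

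Of 30 hypoxia genes, 10 rose (22 adjusted over the list alone), with a median log2 fold change of 0.62. Adm, which encodes the vasodilator adrenomedullin, rose by 2.93 (SE 0.430), Egln3, an oxygen sensor, by 2.41 (SE 0.274), and Bnip3, a mitophagy receptor, by 1.18 (SE 0.161). Of 24 endothelial tip and angiogenic genes, 8 rose (11 adjusted over the list alone), among them Igfbp3, Apln, Mcam and Esm1, with log2 fold changes of 1.96, 2.43, 1.40 and 4.14. Of 21 glial reactivity genes, 9 rose (14 adjusted over the list alone), including the intermediate filaments Vim (1.02) and Nes (1.36). Proliferation genes rose in 4 of 24 (18 adjusted over the list alone), with Top2a, a replication topoisomerase, at 2.30 (SE 0.404). Senescence effectors rose in 4 of 21 and secreted senescence-associated factors in 6 of 23 (10 and 12 adjusted over the list alone). These 6 lists were called by camera and kept the call with an estimated correlation, with an adjusted p of 0.00674 to 0.0101. Glycolysis enzymes rose in 2 of 17 (11 adjusted over the list alone), and the list's call was lost (adjusted p = 0.0939 with an estimated correlation).

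By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, Cdkn1a (1.06, adjusted p = 0.0936), Angpt2 (0.91, adjusted p = 0.147) and Cdkn2a (2.34, adjusted p = 0.316) did not pass at P14. Among the genes that fell were Atp2a3, a calcium pump, at -1.96 (SE 0.231), and Aqp4, the water channel of Müller glia, at -0.90 (SE 0.143). At P14 edgeR called 0 of 21 rod genes (1 at an unadjusted p under 0.05), as did DESeq2 and limma-voom. The lists of ganglion cell, synaptic and cholesterol synthesis genes were called lower by camera, with medians of -0.24, -0.18 and -0.20, and lost the call (adjusted p = 0.163, 0.171 and 0.135 with an estimated correlation). Without control replicate 1 the adjusted p of the ganglion cell and synaptic lists was 0.0997 and 0.0610.

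The 144 higher and 19 lower genes at P14 became 34 and 35 without control replicate 1, 34 and 4 without control replicate 2, 40 and 2 without OIR replicate 1 and 218 and 8 without OIR replicate 2, and the lower count was 12 without control replicate 2 at P30 and 37 without OIR replicate 3 at P30. Leaving out control replicate 1 ended the calls of Vegfa, Gfap, Esm1, Top2a and Aqp4 (adjusted p from 0.0550 to 0.147), control replicate 2 those of Vegfa, Gfap, Edn2, Adm and Top2a (0.0522 to 0.0937), OIR replicate 1 those of Esm1, Top2a and Aqp4 (0.107 to 0.137), and limma-voom those of Edn2 and Esm1 (0.0866 and 0.115). The lens covariate ended the calls of Vegfa, Esm1 and Aqp4 (0.0624 to 0.0659), with log2 fold changes going from 1.16 (SE 0.185) to 0.99 (SE 0.207), from 4.14 (SE 0.739) to 3.43 (SE 0.705) and from -0.90 (SE 0.143) to -0.78 (SE 0.164). The Y-linked covariate ended that of Esm1 (0.0936), at 4.47 (SE 1.03), as did a fit of the P14 libraries alone, at 4.17.

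The P17 comparison falls in the phase of abnormal vessel growth. Glial reactivity genes (21 of 21) and angiogenic genes (16 of 24) rose at P17, and bipolar (11 of 16) and amacrine and horizontal cell markers (12 of 20) fell, by the edgeR quasi-likelihood test. Igfbp3, an insulin-like growth factor binding protein, went from 5.24 ± 0.303 to 42.7 ± 8.27 CPM (SD, n = 3 each), Gfap from 29.0 ± 7.04 to 231 ± 81.9 CPM and Vegfa from 133 ± 6.84 to 320 ± 66.0 CPM. Nefh, the heavy neurofilament of ganglion cell axons, fell from 145 ± 8.12 to 83.1 ± 3.36 CPM. By the edgeR quasi-likelihood test 1555 genes were higher and 1345 lower, of which 748 and 100 by more than 2-fold.

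All 21 tested genes of the glial reactivity list rose at P17, with a median log2 fold change of 2.32. Whole-retina RNA does not show which cells carry these changes. Edn2 rose by 7.54 (SE 0.661) from 10 reads in the controls together, Fgf2 by 3.00 (SE 0.248) and Stat3, a cytokine-activated transcription factor, by 1.07 (SE 0.112). Angiogenic genes rose in 16 of 24 (21 adjusted over the list alone): Angpt2, which destabilises vessels, by 2.32 (SE 0.211), Apln by 3.35 (SE 0.239) and Esm1, a marker of endothelial tip cells with 14 reads in the controls, by 6.13 (SE 0.628). Hypoxia genes rose in 19 of 30, proliferation genes in 17 of 24 and immediate early genes in 13 of 16 (23, 20 and 13 adjusted over the list alone). Pericyte genes rose in 9 of 12 (11 adjusted over the list alone), with Pdgfrb at 0.94 (SE 0.126) and Des, a muscle-type filament, at 2.40 (SE 0.330). Senescence effectors rose in 11 of 21 and secreted factors in 14 of 23 (13 and 17 adjusted over the list alone). The cell cycle inhibitor gene Cdkn1a rose by 1.22 (SE 0.214) and Cdkn2a by 2.42 (SE 0.612), the latter on 73 reads in the OIR libraries and 11 in the controls. The 8 lists named here kept the call with an estimated correlation, with an adjusted p of 0.00674 to 0.0333.

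Microglia and macrophage genes rose in 16 of 20 (17 adjusted over the list alone), including Cd68 (2.51), Lgals3 (2.58) and C1qb (1.62), and the list's call was lost (adjusted p = 0.0801 with an estimated correlation). Endothelial markers rose in 12 of 19 and 1 fell (15 and 1 adjusted over the list alone), with Pecam1 at 1.12. The endothelial list did not pass camera with an estimated correlation (adjusted p = 0.0754). Interferon genes rose in 10 of 25 and matrix genes in 10 of 23 (14 and 12 adjusted over the list alone), and both calls were lost (adjusted p = 0.192 and 0.135 with an estimated correlation).

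Bipolar cell markers fell in 11 of 16, amacrine and horizontal cell markers in 12 of 20 and cholesterol synthesis genes in 12 of 20 (12, 15 and 17 adjusted over the list alone). Gad1, which makes GABA, fell by 0.48 on the log2 scale and the glycine transporter gene Slc6a9 fell by 0.73. These 3 lists kept the call with an estimated correlation, with an adjusted p of 0.0224, 0.0319 and 0.0285. Ganglion cell markers fell in 8 of 16 (11 adjusted over the list alone) and synaptic genes in 12 of 31 with 1 higher (18 and 1), and both calls were lost (adjusted p = 0.0607 and 0.0847 with an estimated correlation). Müller glia markers fell in 7 of 17, among them Glul, Rlbp1 and Kcnj10, and the list as a whole was not called (adjusted p = 0.0698 by camera). Of 21 rod genes 0 were called by edgeR (0 at an unadjusted p under 0.05), DESeq2 or limma-voom, and 3 of 12 cone genes were higher.

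Markers of other tissues moved with these groups. Skeletal muscle and pigment epithelium lists were called lower at P17 by camera, with medians of -0.82 and -0.25, and lost the call (adjusted p = 0.181 and 0.489 with an estimated correlation). Acta1, a skeletal muscle actin, and Myh13, an eye muscle myosin with 32 reads in the controls and 10 in OIR, fell by 0.78 and 1.91 on the log2 scale among 11 muscle genes, and Lrat, a visual cycle enzyme, fell by 0.98 among 13 pigment epithelium genes (2 and 1 adjusted over the list alone). The call of the pigment epithelium list ended with the lens covariate (adjusted p = 0.164), without the 2 OIR libraries richest in lens RNA, where its median was 0.18 (adjusted p = 0.505), and without OIR replicate 1 at P14, control replicates 2 or 3 or OIR replicates 1 or 2 at P17, or control replicate 3 at P30 (0.0509 to 0.149). The call of Lrat ended without control replicate 3 or OIR replicates 2 or 3 at P17 (0.0503 to 0.0661), that of Myh13 without any P14 library, any control at P17 or OIR replicates 1 or 2 at P17 (0.0544 to 0.154), and those of Acta1, Myh13 and Lrat with the Y-linked covariate (0.0893 to 0.523). With the Y-linked covariate the log2 fold changes of Acta1, Myh13 and Lrat were -0.95, -1.73 and -0.87. Their SE was 1.48, 1.7 and 1.57 times that without it. Without the 2 OIR libraries richest in lens RNA, the log2 fold changes of Lrat and Myh13 were -0.96 and -1.19. The call of Myh13 also ended with DESeq2, without a count filter and with the lens covariate (adjusted p = 0.0701, 0.0676 and 0.128). With the lens covariate its log2 fold change was -1.88, with an SE 1.23 times that without it. The call of the pigment epithelium list also ended with RLE scaling and fry (0.0525 and 0.112). The red blood cell list had a median of 1.33 at P14, where its call was lost (adjusted p = 0.424 with an estimated correlation) and also ended without control replicate 1 or OIR replicate 1 (0.0682 and 0.161). At P17 the globin gene Hbb-bs had a log2 fold change of 1.86 and did not pass the edgeR quasi-likelihood test (adjusted p = 0.0711).

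Beside these counts stand the Xist and Ddx3y levels of the P17 libraries: with the Y-linked covariate, chosen after seeing the data, 233 genes were higher and 98 lower at P17, and the calls of Esm1, Des, Cd68, Lgals3, Cdkn1a, Cdkn2a, Gad1, Glul, Rlbp1 and Kcnj10 ended (adjusted p from 0.0641 to 0.519). Their log2 fold changes were 0.607 (Rlbp1) to 0.925 (Esm1) times those without it, and their SE 1.29 (Des) to 2.23 (Esm1) times. Without the 2 OIR libraries richest in lens RNA, an alternative chosen after seeing the data, OIR replicate 3 was the only OIR library left at P17. Its spread was then taken from the other groups. The log2 fold change of Cdkn2a went from 2.42 (SE 0.612) to 2.45 (SE 0.840) and that of Rlbp1 from -0.44 (SE 0.0954) to -0.43 (SE 0.146). Without OIR replicate 3 the lower count was 737, and the call of Cdkn2a ended without control replicate 1 or 2 (adjusted p = 0.0501 and 0.0598).

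**Figure D2:**
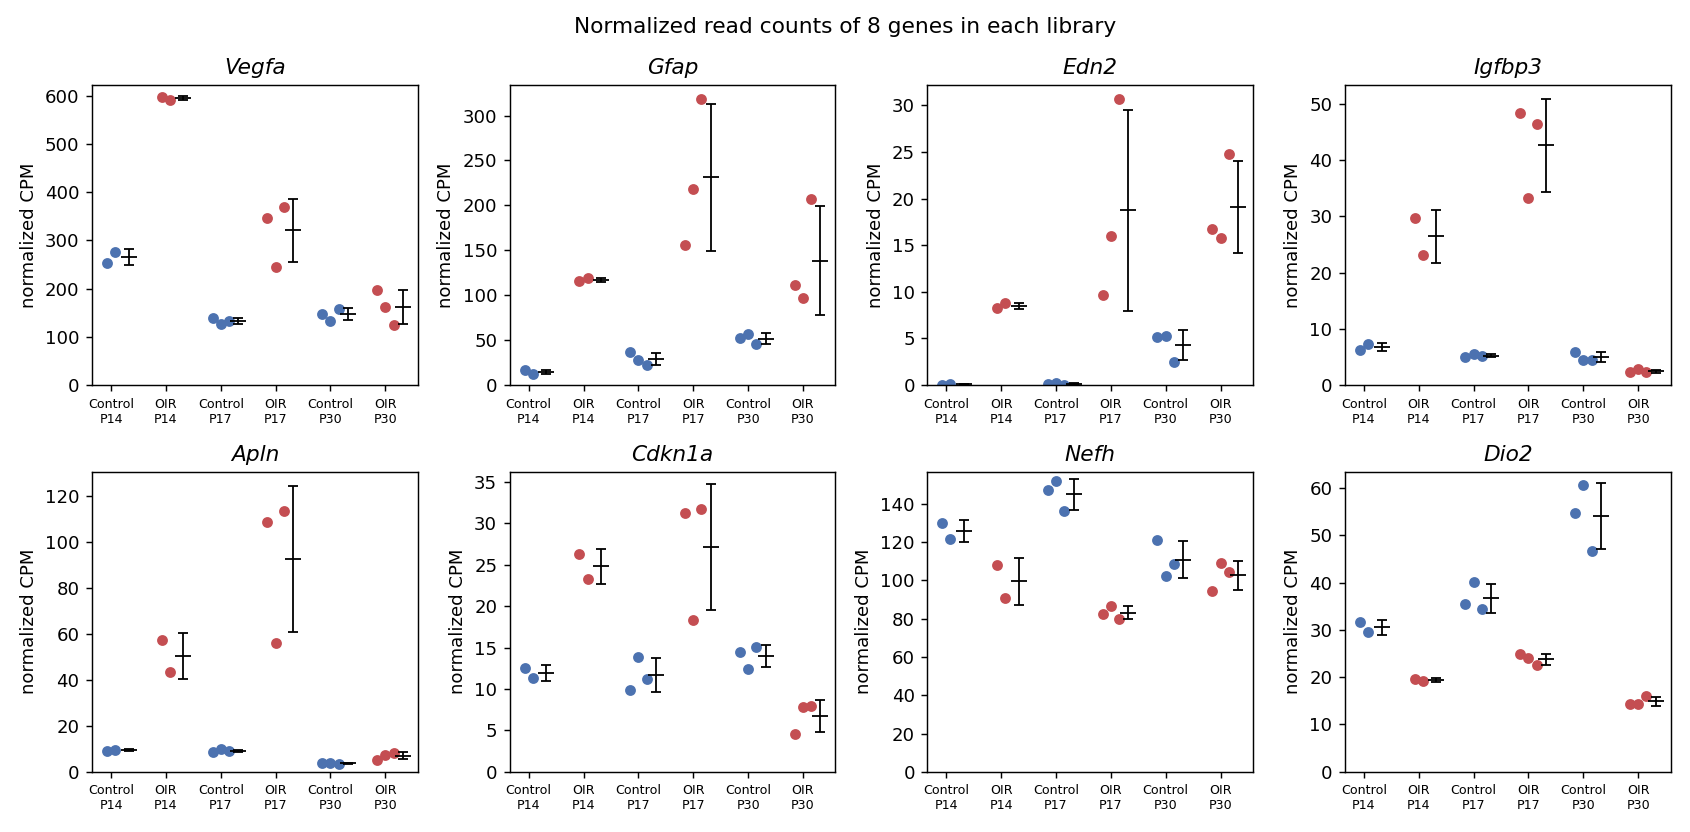
Normalized CPM of 8 genes in each library (points; controls blue, OIR red), with group mean and SD in black. Nefh is lower in all 3 OIR libraries than in all 3 controls at P17, and Dio2 is lower in all 3 OIR libraries than in all 3 controls at P30.

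The P30 comparison asks what differed at the latest age sampled. Dio2, which activates thyroid hormone, fell from 54.1 ± 7.05 to 14.9 ± 0.918 CPM (SD, n = 3 each), a log2 fold change of -1.86 (SE 0.104). Endothelial genes were among those that rose: Cldn5, a tight junction gene, went from 23.2 ± 1.30 to 59.2 ± 7.81 CPM and Aplnr, the apelin receptor, from 0.199 ± 0.0303 to 1.33 ± 0.267 CPM. Gfap was higher by 1.42 (SE 0.318) and Edn2 by 2.15 (SE 0.417), and Vegfa had a log2 fold change of 0.14. The 4 members of the hypoxia list with the smallest p were called higher. These were Ddit4 (0.77), Slc16a3 (0.76), Egln1 (0.38) and Epo (3.18, at an average log2 CPM of -0.88). The remaining members are not reported here. The edgeR quasi-likelihood test called 988 genes higher and 723 lower, of which 171 and 42 by more than 2-fold, against 537 higher and 569 lower with scaling by library totals. A test against a 1.5-fold change called 0 genes higher and 1 lower at P30 (5319 at an unadjusted p under 0.05 in the plain test), and the lower count was 1238 with DESeq2 and 457 with the Y-linked covariate.

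Microglia genes rose in 10 of 20 at P30 (11 adjusted over the list alone), with Trem2, a microglial receptor, at 1.62 (SE 0.256) and C1qc at 1.09 (SE 0.233), and the list's call was lost (adjusted p = 0.202 with an estimated correlation). Glial reactivity genes rose in 7 of 21, endothelial markers in 4 of 19 and interferon genes in 5 of 25 (8, 5 and 6 adjusted over the list alone), and these calls were lost (adjusted p = 0.163, 0.258 and 0.489 with an estimated correlation). ER stress genes fell in 6 of 19 (7 adjusted over the list alone): Xbp1, a transcription factor of the unfolded protein response, fell by 0.89 and Hspa5, an endoplasmic reticulum chaperone, fell by 0.68 (adjusted p of the list = 0.0638 with an estimated correlation). Igfbp3 and Cdkn1a were lower at P30, with log2 fold changes of -1.01 (SE 0.179) and -1.06 (SE 0.226). Of 21 rod genes 0 were called by edgeR (3 at an unadjusted p under 0.05), DESeq2 or limma-voom. With a preset correlation camera called 11 lists higher and 2 lower at P30, with an estimated correlation 0 and 0, and fry 4 and 1.

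A fit of the 6 P30 libraries alone, without the spread of other ages, called 43 genes higher and 27 lower at P30 and ended the calls of Gfap, Trem2, C1qc, Igfbp3 and Cdkn1a (adjusted p from 0.0506 to 0.0878), and leaving out 1 library gave 354 and 196 (control replicate 1), 126 and 100 (control replicate 2), 425 and 385 (control replicate 3) or 383 and 286 (OIR replicate 3). The call of Gfap ended without each of these 4 libraries (adjusted p from 0.0697 to 0.0851), that of Edn2 without control replicate 2 or OIR replicate 3 (0.0557 and 0.0538) that of C1qc without control replicate 2 (0.0800) and that of Aplnr with limma-voom (0.0950).

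**Figure D3:**
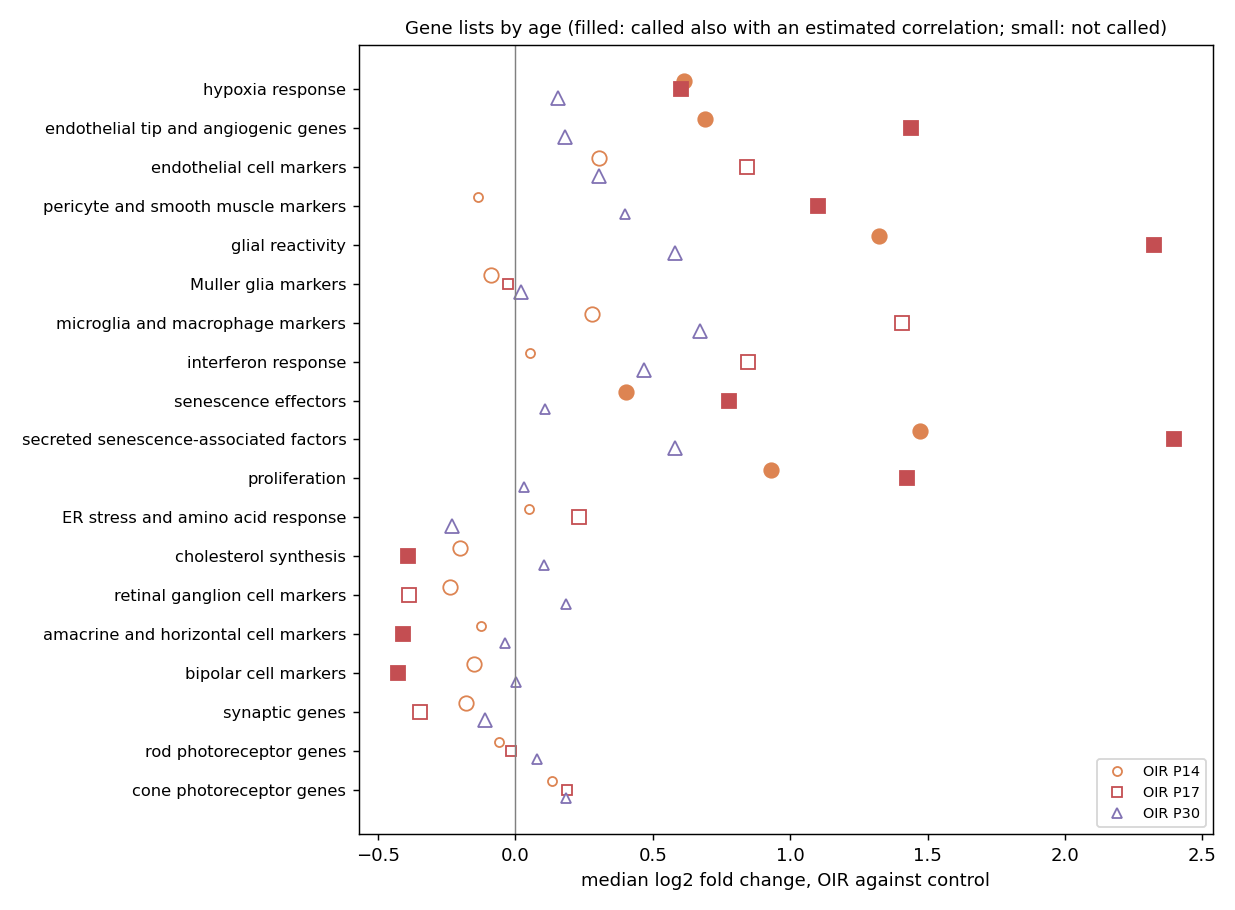
Median log2 fold change of 19 gene lists in OIR against control at P14 (circles), P17 (squares) and P30 (triangles). Filled symbols were called also with an estimated correlation and small symbols were not called, and glial reactivity has medians of 1.32, 2.32 and 0.58.

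The OIR effects of different ages were compared directly. Between P17 and P30 the effect differed for 1850 genes, 1085 with a more positive and 765 with a more negative effect at P30. Edn2 had a difference of -5.39 (SE 0.843) and Kcne1l, a potassium channel subunit, of 2.08 (SE 0.252). In controls alone Edn2 rose by 5.41 (SE 0.711) on the log2 scale from P17 to P30, so its difference does not show a fall within OIR. Between P14 and P17 the edgeR quasi-likelihood test called 0 genes (1698 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 168. A fit of only the compared groups called 6, and edgeR without a count filter called more than DESeq2 did. With the Y-linked covariate, chosen after seeing the data, the P17 to P30 count was 615. The P17 to P30 count was 1200 without control replicate 2 at P17 and 1026 and 1183 without control replicates 2 and 3 at P30. The P14 to P17 count was 44 without control replicate 1 at P14, 15 without OIR replicate 2 at P14, 22 and 6 without OIR replicates 3 and 2 at P30, and 1 without OIR replicate 1 or 2 at P17.

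Across 19905 genes, which are not independent replicates, OIR effects at P14 and P17 had a Pearson correlation of 0.195 and a Spearman correlation of 0.349. For P17 and P30 these were 0.156 and 0.0781, and for P14 and P30 0.133 and 0.219. All of these include the lens and Y-linked genes, such as Cryaa (-10.5 at P14) and Ddx3y (-11.2 at P17). They were not computed without those genes. Without a count filter the Pearson and Spearman correlations were 0.0604 and 0.169, 0.00177 and 0.0126, and 0.0151 and 0.0992 in the same order. Called genes higher at both P14 and P17 numbered 135, where independent lists would share 11.2, and 16 were lower at both against 1.28. For P17 and P30, 190 were higher at both against 77.2, 57 were lower at both against 48.9, and 108 moved in opposite directions against 123. Leaving out control replicate 1 at P14 gave 0.120 and 0.221 for P14 and P17 and a Pearson correlation of 0.0822 for P14 and P30, and leaving out OIR replicate 1 at P14 gave Pearson correlations of 0.0912 and 0.0621 and, for P14 and P30, a Spearman correlation of 0.109. For P17 and P30 the Spearman correlation was 0.0117 without control replicate 1 at P17, 0.173 without control replicate 2 at P17 and 0.0383 without OIR replicate 2 at P30, where the Pearson correlation was 0.0602.

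Control retinas of consecutive ages were also compared. Their lens share was 0.657% (95% Wilson interval 0.654 to 0.659) or less at P17 and 5.93% (5.92 to 5.94) or more at P30, and their Yam1 share was lower at P14 than at P17. Gm24187, annotated as a microRNA gene, went from 1.17 ± 0.554 CPM (SD, n = 2) at P14 to 149 ± 73.3 CPM (n = 3) at P17, and Tgfbr3l fell from 20.8 ± 6.09 to 1.29 ± 0.763 CPM. From P17 to P30 Edn2 rose in controls by 5.41 (SE 0.711), the lens channel gene Mip by 6.32 (SE 1.42), and Aplnr fell by 5.79 (SE 0.381). The edgeR quasi-likelihood test called 3643 genes higher and 4355 lower at P17 than at P14, and 2965 higher and 2659 lower at P30 than at P17. Scaling by library totals alone moved the median log2 fold change of all genes to -0.12 and -0.23 and gave 1108 higher and 5479 lower genes at P30 than at P17. Leaving out control replicate 1 or 2 at P14 moved the count of genes higher at P17 to 2410 and 2234.

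Genes that rose in controls from P17 to P30 had a median log2 OIR effect of 0.00 at P14, and those that fell one of -0.08 (camera p = 0.00698, and p = 0.214 with an estimated correlation). The second median was -0.02 without control replicate 1 at P14, where the direction of its camera test reversed, and the first was 0.03 without control replicate 2.

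On mm10, Vegfa lies on chromosome 17 from 46016993 to 46032369, Gfap on chromosome 11 from 102887336 to 102900912, Edn2 on chromosome 4 from 120161206 to 120167360 and Igfbp3 on chromosome 11 from 7206086 to 7213923. Nefh lies on chromosome 11 from 4938754 to 4948064 and Dio2 on chromosome 12 from 90724552 to 90738438, and all 6 are annotated as protein-coding genes.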

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

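The tests of lens carry-over, of crystallins raised in retinal cells, of sex, and of preparation and age were chosen only after the related values had been seen, as were both covariates.

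The OIR effect differed between P17 and P30, by a test of the difference itself, for 1085 genes in the positive and 765 in the negative direction. Genes named at both ages or by their size in this test were examined. Effects were more negative at P30 for Esm1 (-5.47), Edn2 (-5.39), Fgf2os (-4.43), Igfbp3 (-4.04), Lad1 (-3.40), Angpt2 (-2.33), Cdkn1a (-2.27), Fgf2 (-1.60), Gadd45b (-1.39) and Vegfa (-1.14). They were more positive for Kcne1l (2.08), Aplnr (1.89), Nrtn (1.73) and Isl1 (1.02). By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p of these genes ran from 5.03e-08 (Igfbp3) to 0.0388 (Aplnr). In controls alone, Edn2 rose by 5.41 and Aplnr fell by 5.79 on the log2 scale from P17 to P30. Their differences therefore do not show a fall of Edn2 or a rise of Aplnr within OIR. The call of Aplnr ended when any 1 of 9 libraries was left out (control replicate 2 and OIR replicates 1 and 2 at P14, control replicate 2 at P17, all 3 controls and OIR replicates 2 and 3 at P30; adjusted p from 0.0504 to 0.102). That of Esm1 ended without control replicates 2 or 3 or OIR replicate 1 at P17, any control at P30 or OIR replicate 1 at P30 (0.0503 to 0.134), and that of Fgf2os without control replicates 1 or 3 at P17 or 1 or 2 at P30 (0.0519 to 0.0693). With the Y-linked covariate the count of genes was 615 and the calls of Aplnr, Esm1 and Fgf2os ended (0.101, 0.107 and 0.0726), with log2 differences of 1.89, -5.16 and -4.62 and an SE 1.11, 1.09 and 1.16 times that without it. Leaving out the 2 OIR libraries at P17 richest in lens RNA, also chosen after seeing the data, kept OIR replicate 3 as the only OIR library of that age. The log2 difference of Nrtn was then 1.53, with its SE going from 0.360 to 0.466. With limma-voom the calls of Aplnr and Fgf2os ended (0.224 and 0.0821). The P17 groups in this difference also differ in sex.

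Among lists called under both correlations, the median difference was -1.49 for glial reactivity, -1.37 for proliferation, -0.97 for angiogenic genes, -0.62 for ER stress and -0.37 for senescence effectors. It was 0.59 for ganglion cell, 0.46 for cholesterol synthesis and 0.34 for bipolar cell genes. Of 50 splits of the samples within ages, drawn from 200, only the real 1 gave 1850 genes. The other drawn splits that kept the P17 groups while mixing those at P30 gave 320 to 1173. Those that mixed the P17 groups gave 26 or fewer. The splits exchange OIR and control within an age, so they cannot decide whether the effect differs between ages.

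The first pattern is the unequal lens signal. Within groups, Mip, Lim2, Bfsp1 and Bfsp2 followed Cryaa over the 16 libraries with Pearson correlations of 0.932, 0.936, 0.896 and 0.813 (median 0.914; Spearman 0.947, 0.929, 0.915 and 0.909; adjusted exact permutation p of 0.00598 or less, two-sided), and with 0.877, 0.895, 0.807 and 0.648 without control replicate 1 and OIR replicate 3 at P17. That is consistent with lens tissue carried into the dissected retina. Of 19 tested lens genes 5.26% were higher in every OIR than in every control library at P17, where chance gives 5%, but these genes move together and the lens share of OIR replicate 3 alone fixes that outcome, so crystallins raised by OIR in retinal cells stay open. With the lens covariate 98.8% of 2898 P17 calls outside the lens list kept their sign and at least 50% of their log2 fold change. The median SE went from 0.139 to 0.169 and 2008 stayed called. The covariate is the mean log2 level of the lens list, with a single slope for all groups. Libraries with little lens RNA therefore also set that slope, while carried-over RNA would add by its share of counts. These values argue against a source that follows the log2 lens level, and cannot decide on one that follows the share.

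The second pattern is that Xist and Y-linked genes separate OIR from control completely at P17. Of 2896 genes called at P17, 86.6% had the same sign at P14, where both OIR libraries carry Y-linked reads, with 79.5% to 88.7% when 1 P14 library was left out. The share was 88.7% without control replicate 2, when no P14 library has high Xist, which argues against sex as the source of the P17 calls as a set. With the Y-linked covariate 94.2% kept their sign and at least 50% of their log2 fold change (median ratio 0.897). The median SE went from 0.139 to 0.206 and 328 stayed called, so most calls ended as the error grew. Sex and OIR coincide at P17, and the growth of the error goes with this overlap. The slope of the covariate therefore rests mainly on control at P14 and OIR at P30, where replicates differ in sex. Igfbp3, Apln, Mcam and Egln3 kept their calls at P14 without control replicate 2 and at P17 with the covariate, which argues against sex as their source, while for genes whose P17 call ended sex stays open.

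The third pattern is the difference of P14 from later libraries. The 88 small structural RNA genes had a median log2 fold change of -2.08 from P14 to P17 in controls and -2.28 in OIR. By class, snRNA, snoRNA and rRNA genes had -1.82, -2.24 and -1.84 in controls and -1.40, -2.61 and -2.24 in OIR, while misc_RNA genes had -0.05 and 0.13. The requirement that every class shift was added after these values were seen; with the overall median alone, the values would have favoured preparation over age. Preparation and age cannot be told apart, because no age holds libraries of both kinds.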

How the results depend on the processing

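The lens covariate, the Y-linked covariate, leaving out the lens list and Yam1, leaving out 2 OIR libraries at P17 and the crossed replicate block at P14 were chosen after seeing the data. Counts of genes or lists are given below where they left a range of 1.5 times the reported count, and the cause was not tested unless it is stated.

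With RLE scaling all 182 gene values tested again kept their direction and side of the threshold, with library totals 177, without a count filter 177, with a stricter filter 177 of 177, with DESeq2 175 of 181, with limma-voom 162 and with a replicate block 174. With the lens covariate this held for 156, with the Y-linked covariate for 134, at an adjusted p under 0.01 for 133, with only the groups compared for 134 of 178 and with the 1.5-fold test for 87. A stricter threshold calls fewer genes by its construction.

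Scaling by library totals gave 537 genes higher and 569 lower at P30, and 1108 higher and 5479 lower in control at P30 than at P17. Without a count filter there were 507 genes higher and 170 lower at P14, 570 with a different effect at P14 and P17, Pearson and Spearman correlations of 0.0604 and 0.169 (P14 with P17), 0.00177 and 0.0126 (P17 with P30) and 0.0151 and 0.0992 (P14 with P30), and a median of 0.0149 at P14 for genes that rose in controls from P17 to P30. The lens covariate gave 48 higher and 4 lower at P14, 1856 higher in control at P30 than at P17, 1 list lower at P30, and a lens list median of -0.13 at P17, reversed because the covariate is built on it. The Y-linked covariate gave 93 higher and 9 lower at P14, 233 and 98 at P17, 457 lower at P30, 615 genes for the difference between P17 and P30, 1 list lower at P30, and Eif2s3y reversed at 0.65 at P17, again by construction. Without the 2 OIR libraries richest in lens RNA there were 824 higher and 414 lower at P17, differences for 4 (P14 to P17) and 553 genes (P17 to P30), and Cryab reversed at -0.0654.

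At an adjusted p under 0.01 there were 49 higher and 3 lower at P14, 846 and 613 at P17, 141 and 90 at P30, 515 for the difference between P17 and P30, 2303 higher in control at P17 than at P14, and 1773 higher and 1554 lower at P30 than at P17. The edgeR test against 1.5-fold gave 30 and 2 at P14, 385 and 25 at P17, 0 and 1 at P30 (5319 at an unadjusted p under 0.05 in the plain test), 64 for the difference, 484 and 1315 in control at P17 against P14, and 233 and 279 at P30 against P17. DESeq2 gave 275 and 93 at P14, 1238 lower at P30 and 168 for the difference between P14 and P17. Only the groups compared gave 250 and 32 at P14, 43 and 27 at P30, and 6 for the difference between P14 and P17. With an estimated correlation camera called 6 lists higher and 0 lower at P14, 8 and 3 at P17, and 0 and 0 at P30, where fry called 4 and 1.

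Leaving out each library in turn gave 34 to 218 higher and 2 to 37 lower genes at P14, 1050 to 1906 higher and 737 to 1817 lower at P17, 126 to 1230 higher and 100 to 949 lower at P30, 0 to 44 for the difference between P14 and P17, 1026 to 2061 for that between P17 and P30, 2234 to 4395 higher in control at P17 than at P14, and 1 to 3 lists lower at P30. Where 1 library of a group was left, it was assumed to vary like the other groups. Pearson correlations ranged from 0.0912 to 0.246 (P14 with P17), 0.0602 to 0.192 (P17 with P30) and 0.0621 to 0.168 (P14 with P30), and Spearman correlations from 0.221 to 0.383, 0.0117 to 0.173 and 0.109 to 0.240. Medians at P14 of genes that changed in controls from P17 to P30 ran from -0.0202 to 0.0310 for those that rose and from -0.130 to -0.0235 for those that fell, where the direction of the test reversed without control replicate 1. The direction of the extracellular matrix list at P14 also reversed without that library (median 0.0733, with a range of -0.0142 to 0.773 over the libraries left out).

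Depth limits the genes with few reads, such as Cdkn2a, with 11 reads in the controls and 73 in OIR at P17.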

Other observations

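No test in this part was chosen after its result was seen, and the glucocorticoid genes were listed after the fall of Dio2 had been noticed.

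Fam107a and Arrdc2, which glucocorticoids can induce, and Dio2 were lower in OIR at P30, with log2 fold changes of -1.04, -1.40 and -1.86. Fam107a was singled out after its value was seen. In a fit of the P30 libraries alone the calls of Fam107a and Arrdc2 ended (adjusted p = 0.0750 and 0.0680), and that of Fam107a also ended without control replicates 1 or 3 or OIR replicate 3 (0.0647 to 0.0827). A candidate explanation is a fall of glucocorticoid-dependent transcription in OIR. The set of 12 other glucocorticoid-responsive genes had a median log2 fold change of -0.19, with 1 gene higher and 2 lower. By camera the set was not called (p = 0.111, and 0.296 with an estimated correlation), which leaves the hypothesis open.

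For comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. At P17 the real split gave 2900 calls and the highest other 17, at P30 1711 and 0, and for controls at P30 against P17 5624 and 0. In each of the 3 comparisons 1 split, the real one, gave as many calls. All other splits mix the compared groups, so a difference between these groups adds to the spread and keeps those counts low. At P17 the real split also separates the libraries by Xist and Ddx3y, so its count cannot tell OIR from sex.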
